A study of Homo sapiens with 6 samples.

How the data were processed

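Polyadenylated RNA was sequenced from Jurkat cells, an established human T cell acute lymphoblastic leukemia line grown in suspension. There were 6 libraries, 3 from cells given the solvent DMSO and 3 from cells given P5091, an inhibitor of the deubiquitinase USP7, for 24 h. The sample labels give no dose and, for DMSO, no time. The column headers write 24 h for every library and a P5091 dose of 10 with the unit mM, which was not checked against another source. Each library was assigned to its group and replicate from its title.

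The submitters' processing notes name bcl2fastq, TopHat, HTSeq and edgeR and the genome build hg19; versions and settings are not given in the sources used here. The labels' descriptions differ on the library type. Per the sample protocols the libraries were strand-specific (dUTP) and read from a single end. The series design text speaks of unstranded, paired-end libraries across the whole project. The strand setting of the counting is not given in the sources used here, so reads of a gene and of an antisense or overlapping partner may not be separated. Of the 14258 listed genes, 5084 overlap another listed gene. Near-identical copies and pseudogenes can also share reads, as in HSPA1A and HSPA1B, HSPA6, FTH1, FTL, NPM1, HNRNPA1, the metallothioneins and the ribosomal proteins, and such values are uncertain.

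The authors deposited values in CPM, read counts scaled to the library total, for each library and gene, which sum to between 997530 and 997736 per library. The deposited CPM columns show no scaling factor between libraries. The authors' deposited log2 fold change and average log2 CPM, their likelihood-ratio score and their p-value and adjusted p-value come from edgeR, per the submitters' processing notes and the file headers. The authors also marked genes as higher or lower. Every listed gene exceeds 1 CPM in at least 2 libraries; a rule for leaving out low genes is not given in the sources used here. Coordinates are those of the authors' table (hg19). Gene names are those of the table too.

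The values of each library are whole multiples of a step, and 100% of them came out whole within a tolerance of 0.05 read. Read from that step, the CPM rest on about 70917000, 83879000 and 83939000 reads in DMSO replicates 1 to 3 and on about 81964000, 86524000 and 52016000 in P5091 replicates 1 to 3. At 10 CPM this depth gives a counting error of 3.40% to 4.38% per library, which covers counting error only. No count model was run on these values, and the planned count tests were replaced by the test that CPM need.

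The main test was limma (version 3.58.1, R 4.3.3) on log2(CPM + 1), with both groups in the fit, no covariate and moderated variances with an intensity trend. It was two-sided, with the Benjamini-Hochberg adjustment over all 14258 genes and a threshold of 0.05. Log2 changes are on the log2(CPM + 1) scale, which understates the change of genes with low values. The plan for normalized values had named limma and this pseudocount; the trend was not in the plan and was set before any output was seen. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. An exact permutation of 3 libraries against 3 cannot give a two-sided p under 0.10.

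Before the data were examined, 30 gene lists were fixed, and 28 had at least 1 measured member. They were tested with limma's camera at a preset inter-gene correlation of 0.01 on log2(CPM + 1), with Benjamini-Hochberg adjustment over the 28 lists. The precision weights planned for this test need counts and were left out. Camera compares a list with all other genes; it was repeated with an estimated correlation. Limma's fry, also run, is self-contained: it asks whether a list's members move on balance in 1 direction, without comparing them with other genes.

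The rule for named genes was also fixed before the data were examined. It takes USP7 and SRSF6. It adds the 5 genes of largest rise and the 5 of largest fall past the threshold, among named genes with a mean of at least 5 CPM and groups that do not overlap. From each main list, and from each other list that passed camera, it takes the 2 members of smallest adjusted p. This named 53 genes. Most were picked for a small p, so a call kept under other settings was largely built in and says little about other genes. Members named beyond the rule, to spell out a small count or as a contrast, were chosen after their values were seen. Some list members are counted but not reported by name here.

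The procedure was tested on simulated data for P5091 against DMSO with 14258 genes, 200 of them changed. It recovered 70% of changes of 0.25 on the log2 scale, 94% of those of 0.5 and 100% of those of 1 and of 2. It called 14 of 14058 unchanged genes, which made up 7.14% of its calls. The simulation gave all genes a common dispersion and changed few of them, while 71.3% of the real genes were called. These shares may therefore not carry over to the data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures. GC content and transcript length came from the GENCODE transcripts of the GRCh38 annotation, matched by gene for 97.5% of the genes; no coordinates were taken from it.

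The alternatives were pseudocounts of 0.1 and 0.5, RLE size factors, upper-quartile factors, a filter of at least 1 CPM in 3 libraries, a replicate block, leaving out each library, an adjusted p threshold of 0.01 and a minimum log2 change of 1. A variance without the intensity trend, a correction for GC content and length, a minimum mean of 5 CPM and a minimum of 3 measured members per list were added after seeing the data. Exon inclusion and the project's other experiments were not analysed here.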

Results

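Gene expression was measured by RNA sequencing of polyadenylated RNA in Jurkat cells, a human T cell acute lymphoblastic leukemia (T-ALL) line. The 3 DMSO libraries served as controls for 3 libraries of cells given P5091 for 24 h. P5091 inhibits USP7, an enzyme that removes ubiquitin from proteins. The values were the authors' CPM for 14258 genes, resting on about 52016000 to 86524000 reads per library. The series concerns how protein modification governs the exon-skipping machinery in this leukemia, and it names the splicing factor SRSF6. The comparison asks how gene expression differs between cells given P5091 and cells given DMSO. USP7 activity is not measured by these values.

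The messengers of both USP7 and SRSF6 were lower in P5091. USP7 (ENSG00000187555, chromosome 16, 8985951 to 9058371, hg19) went from 540.5 ± 10.5 CPM in DMSO to 399 ± 6.1 CPM in P5091 (mean ± SD, n = 3 each). Its log2 change was -0.44 (SE 0.0315; limma, adjusted p = 1.3e-09). SRSF6 (ENSG00000124193, chromosome 20, 42086568 to 42092245, hg19), a serine/arginine-rich (SR) protein that acts in exon choice, went from 262 ± 5.83 to 205 ± 7.29 CPM (n = 3 each), a log2 change of -0.35 (SE 0.034; limma, adjusted p = 6.07e-08). All 3 P5091 libraries lay below all 3 DMSO libraries for both genes, and the groups did not overlap in 72.9% of all genes. P5091 acts on the USP7 protein, so the level of its messenger does not check the labels.

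The largest rise among named genes of at least 5 CPM was that of CLU, which encodes the extracellular chaperone clusterin (chromosome 8, 27454434 to 27472548, hg19). It went from 2.54 ± 0.0574 to 72.8 ± 1.39 CPM (n = 3 each), 28.7 times the DMSO mean, with a log2 change of 4.38 (SE 0.0429; limma, adjusted p = 4.28e-21). HSPA6, a stress-inducible chaperone, followed with a log2 change of 3.59, from 1.02 to 23.1 CPM. JUN, a subunit of the AP-1 transcription factor, rose from 9.95 to 99.5 CPM (log2 change 3.20), DUSP8, a phosphatase of MAP kinases, from 2.63 to 27.4 CPM (2.97), and TUBA4A, an alpha tubulin, from 10.9 to 58.0 CPM (2.31). The largest falls were in MIR210HG, a microRNA host transcript, from 13.0 ± 0.76 to 1.55 ± 0.106 CPM (log2 change -2.46, SE 0.0585; limma, adjusted p = 9.52e-16; n = 3 each), and PFKFB4, a regulator of glycolysis, from 52.5 to 11.9 CPM (-2.06). IGLL1, a surrogate immunoglobulin light chain, fell from 335 to 86.7 CPM (log2 change -1.94), GPR56, an adhesion receptor, from 18.5 to 4.5 CPM (-1.83), and SDK2, a cell adhesion protein, from 10.1 to 2.25 CPM (-1.78). Reads of HSPA6 can be shared with a near-identical copy, and TUBA4A overlaps another gene on the opposite strand.

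**Figure D1:**
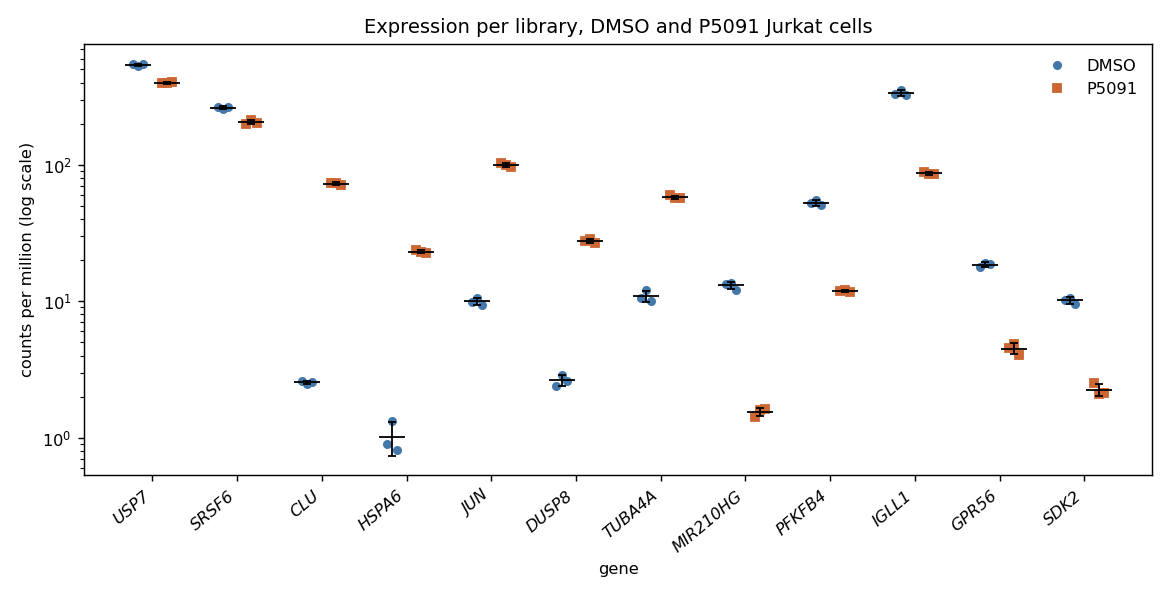
CPM on a log scale for USP7, SRSF6 and the 10 genes of largest rise or fall, with a point per library (circles DMSO, squares P5091), bars at the mean and error bars of 1 SD (n = 3). In each gene all 3 P5091 libraries lie on the same side of all 3 DMSO libraries, which the naming rule required of those 10. For CLU the means are 2.54 and 72.8 CPM.

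Most of the listed genes differed between the groups, by small amounts. With limma 10163 of 14258 genes (71.3%) passed an adjusted p of 0.05, of which 5649 rose and 4514 fell. The median size of the called changes was 0.28 on the log2 scale, and 81.3% of them were under 0.5. Only 216 genes rose and 81 fell by at least 1. The groups did not overlap in 72.9% of all genes, where chance gives 10%. The authors' deposited table marks 4654 genes as higher and 4444 as lower, all with an adjusted p of at most 0.00996. An adjusted p under 0.05 is given to 10158 genes in the authors' deposited table, 5165 higher and 4993 lower; 9676 of these passed limma too, all in the same direction.

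**Figure D2:**
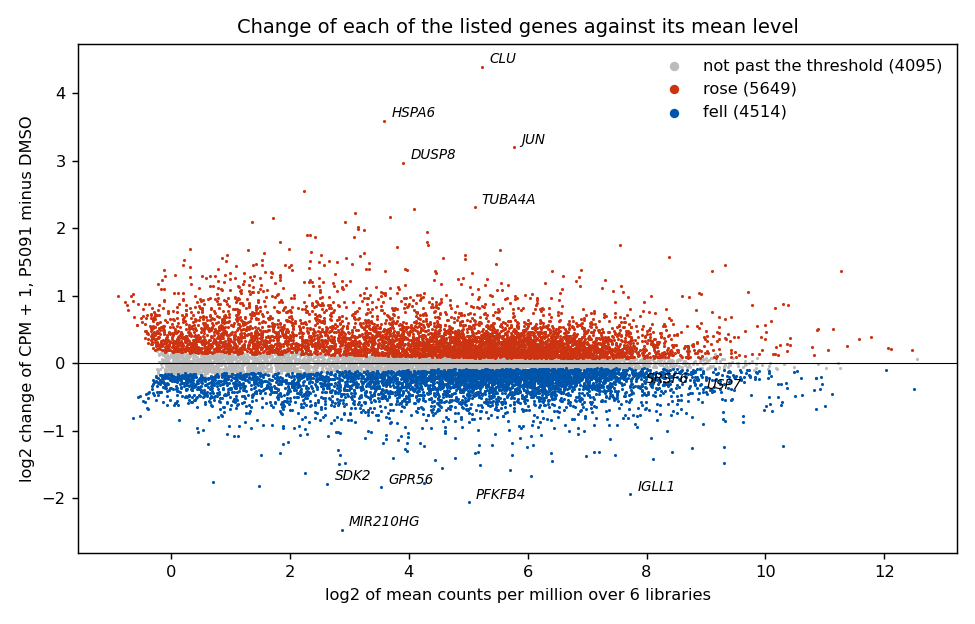
Log2 change of CPM + 1 (P5091 minus DMSO) against the log2 of mean CPM over the 6 libraries, with a point per gene; red genes rose (5649), blue genes fell (4514) and grey genes did not pass the threshold. Changes spread on both sides of 0 at all levels. Among named genes with a mean of at least 5 CPM and groups that do not overlap, CLU is highest and MIR210HG lowest.

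Mitochondrially encoded messengers and genes listed as markers of other cell types moved with the treatment too, and the gene group counts stand beside these values. Mitochondrial genes took 2.32% to 3.07% of the CPM in DMSO and 3.22% to 3.31% in P5091. Of 13 mitochondrial messengers 10 rose, and MT-ND4L, MT-CO1 and MT-CO3 did not pass (median log2 change 0.38). These messengers encode subunits of the respiratory chain and ATP synthase. Limma's camera gave this list adjusted p = 0.0547, and 0.0076 to 0.0719 without 1 library. With an estimated correlation camera gave adjusted p = 0.624. Of the genes listed as such markers, the B cell gene CD79A (log2 change 1.19) and the collagen gene COL1A1 (1.40) were measured. The intermediate filament gene VIM (0.68) was measured too, and all 3 rose. VIM stood at 460 CPM in DMSO, so it does not set another cell type apart from these cells. The epithelial and fibroblast list thus rested on COL1A1 and VIM (camera, adjusted p = 0.0299, and adjusted p = 0.195 with an estimated correlation), and the B cell list on CD79A (camera, adjusted p = 0.102). None of the listed myeloid or erythroid markers was among the genes analysed here. For the 28 lists with measured members, the counts adjusted over the list alone equalled those adjusted over all genes, except in the core spliceosome.

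Genes of the splicing machinery fell more often than they rose. Of 13 measured SR splicing factors, which bind exons and guide splice site choice, 10 fell and none rose (median log2 change -0.25). SRSF1 fell from 440.2 ± 10.6 to 289 ± 11.7 CPM (n = 3 each; log2 change -0.61) and SRSF7 from 231 ± 1.41 to 166 ± 2.1 CPM (-0.48), while SRSF9 (-0.04), SRSF8 (0.02) and TRA2A (0.01) did not pass. The SR list lay lower than other genes by limma's camera (adjusted p = 0.00143, and adjusted p = 0.34 with an estimated correlation). In the core spliceosome 18 of 40 members fell, 5 rose and 17 did not pass; adjusted over the list alone 17 fell and 5 rose, and with RLE size factors 23 fell and 5 rose. SNRPA, a protein of the U1 particle, fell by 0.74 on the log2 scale and the helicase gene DHX15 by 0.30, whereas SF3B4, DHX16, PRPF6, SNRPA1 and CDC5L rose. The median log2 change was -0.06 (camera, adjusted p = 0.0299, and adjusted p = 0.385 with an estimated correlation). Without P5091 replicate 2 the camera adjusted p was 0.0501. Of 20 hnRNP genes, whose proteins bind nascent transcripts, 11 fell and 5 rose (HNRNPLL, HNRNPH2, HNRNPH1, HNRNPUL2 and HNRNPM), with HNRNPDL at -0.54 and HNRNPH3 at -0.45; with RLE size factors 14 fell and 4 rose. The hnRNP list passed camera at an adjusted p of 0.0299, with adjusted p = 0.488 with an estimated correlation and 0.0559 without P5091 replicate 1.

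Proteasome genes rose almost as a whole. Of 33 subunit genes 31 rose and none fell (median log2 change 0.34), with PSMD7 (-0.06) and PSMA6 (0.01) not past the threshold; with RLE size factors 30 rose and 1 fell. ADRM1, a ubiquitin receptor of the proteasome, went from 119 ± 4.08 to 192 ± 1.62 CPM (n = 3 each; log2 change 0.68), and PSMD2, a scaffold subunit, from 496 ± 6.01 to 778 ± 13.8 CPM (0.65). Limma's camera gave adjusted p = 2.88e-07, and adjusted p = 0.258 with an estimated correlation. Among 7 ubiquitin genes and related enzymes 2 rose and 2 fell, USP7 among the latter (median log2 change 0.07; camera, adjusted p = 0.975).

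Heat shock chaperones went both ways. Of 20 genes 7 rose, among them the inducible chaperone HSPA1B (log2 change 1.60) and the co-chaperone BAG3 (0.97), and 11 fell, among them the mitochondrial chaperonin HSPD1 (-0.70) and HSP90AB1 (-0.45). The median was -0.18, the mean 0.07 and the direction of camera down (adjusted p = 0.278), so these differ in sign. Genes of amino acid supply and the integrated stress response, targets of the transcription factor ATF4, mostly fell: 21 of 29 fell (median log2 change -0.29). CBS, an enzyme of cysteine synthesis, went from 120.3 ± 4.85 to 47.6 ± 1.06 CPM (n = 3 each; log2 change -1.32). The 5 that rose were PPP1R15A (1.68), which directs dephosphorylation of an initiation factor of translation, and DDIT3, ATF5, ATF3 and SLC3A2. This list passed limma's camera (adjusted p = 0.000155, and adjusted p = 0.167 with an estimated correlation). In the unfolded protein response of the endoplasmic reticulum 7 of 20 genes rose and 7 fell, with the chaperone gene CALR at 0.35 and EDEM1, which acts in the disposal of misfolded proteins, at -0.37. Its median was 0.02, which turned to -0.01 with RLE size factors, its mean was -0.01 and camera pointed down (adjusted p = 0.673).

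Antioxidant and lysosomal genes rose. Of 20 measured NRF2 targets 15 rose and 2, TKT and ABCC1, fell (median log2 change 0.53). NQO1, a quinone reductase, went from 8.32 ± 0.17 to 31.4 ± 0.561 CPM (n = 3 each; log2 change 1.80), and FTL, the ferritin light chain, from 340 ± 8.54 to 935 ± 23.1 CPM (1.46). Camera gave adjusted p = 0.000122, and adjusted p = 0.167 with an estimated correlation. Of 18 autophagy and lysosome genes 16 rose and ATG9B fell, while UVRAG (-0.03) did not pass. The lysosomal proteases CTSD and CTSB rose by 1.27 and 0.93 on the log2 scale, and the median was 0.56 (camera, adjusted p = 4.03e-05, and adjusted p = 0.0799 with an estimated correlation). SQSTM1 is a member of both lists. The metallothionein genes MT2A (1.25), MT1F (0.81) and MT1X (0.41) rose and the zinc exporter gene SLC30A1 (-0.34) fell; this list of 4 did not pass camera (median 0.61; adjusted p = 0.124).

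Of 24 p53 targets 15 rose, 3 fell (CCNG1, ZMAT3 and MDM2) and 6 did not pass (median log2 change 0.18). CDKN1A, an inhibitor of cyclin-dependent kinases, went from 1.7 ± 0.213 to 6.22 ± 0.163 CPM (n = 3 each; log2 change 1.42), and TP53INP1 from 12.3 ± 0.769 to 25.3 ± 1.52 CPM (0.99). The list passed limma's camera (adjusted p = 0.022, and adjusted p = 0.167 with an estimated correlation). In the BCL2 family and inhibitors of apoptosis 11 of 19 rose and BIK, BCL2L11 and BIRC3 fell (median 0.13; camera, adjusted p = 0.179). The cell death promoting genes BBC3, also a p53 target, and BMF rose by 0.80 and 0.66 on the log2 scale.

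Cholesterol synthesis genes had the lowest median change of the fixed lists. Of 22 measured genes 20 fell (median log2 change -0.79) and only PMVK rose (0.24). HMGCS1, which makes the precursor of mevalonate, went from 932 ± 21.8 to 333 ± 4.35 CPM (n = 3 each; log2 change -1.48), and ACAT2, an acetyl-CoA acetyltransferase, from 402 ± 7.31 to 150 ± 5 CPM (-1.42). Camera gave adjusted p = 6.43e-10, and the list still passed with adjusted p = 0.0322 with an estimated correlation.

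Genes of S phase and of mitosis moved in opposite directions. Of 37 DNA replication genes 31 fell and RRM2 and GINS4 rose (median log2 change -0.27). The helicase subunit genes MCM2 and MCM7 fell, from 459.6 ± 11.2 to 274 ± 5.76 CPM (log2 change -0.74; n = 3 each) and from 779.6 ± 21.6 to 474 ± 6.72 CPM (-0.71). All 25 genes of G2 and mitosis rose (median 0.48), 24 of them past the threshold with RLE size factors. CDC20, an activator of the anaphase-promoting complex, rose by 0.77 on the log2 scale and the kinesin gene KIF20A by 0.64. Camera gave adjusted p = 1.64e-07 for both lists, and adjusted p = 0.167 with an estimated correlation for both. Of 5 measured replication-dependent histone genes, whose messengers mostly lack the tail used for selection, HIST1H2AC, HIST2H2BE and HIST1H2BD rose and HIST1H2BK fell (median 0.32; camera, adjusted p = 0.21).

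All 24 genes of ribosome biogenesis fell (median log2 change -0.44). NPM1, a nucleolar chaperone, fell from 1379 ± 67.7 to 842 ± 26.3 CPM (n = 3 each; log2 change -0.71) and MYBBP1A by 0.68. Camera gave adjusted p = 6.43e-10, and adjusted p = 0.0322 with an estimated correlation. Of 45 cytosolic ribosomal protein genes 29 fell, RPS18 rose and 15 did not pass, with small sizes (median -0.13, RPS2 -0.37, RPL4 -0.30; camera, adjusted p = 0.00022, and adjusted p = 0.507 with an estimated correlation). In the NOTCH1 pathway and its T-ALL targets 10 of 15 genes fell, IL7R rose and NOTCH1 itself did not pass (0.04). MYC went from 354 ± 10.8 to 217 ± 4.42 CPM (n = 3 each; log2 change -0.71), and the pseudokinase gene TRIB2 fell by 0.68. The list had a median of -0.29 (limma's camera, adjusted p = 0.00482, and adjusted p = 0.172 with an estimated correlation).

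T cell receptor genes were mixed, while immediate early and interferon-stimulated genes rose. Of 21 T cell receptor and signalling genes 13 rose and 6 fell (median log2 change 0.23; camera, adjusted p = 0.123). TRAC, the receptor's alpha constant region, went from 60.6 ± 1.24 to 126 ± 2.83 CPM (n = 3 each; log2 change 1.05) and PTPRC, the phosphatase CD45, from 623 ± 25.5 to 1131 ± 18.2 CPM (0.86), while CD4 (-0.60) and RASGRP1 (-0.59) fell. Of 15 T-ALL and thymocyte transcription factors LMO2, TAL1, RUNX1, GATA3 and LEF1 rose and IKZF1, TCF7, TCF12, LMO1 and RUNX3 fell; with RLE size factors 3 rose and 6 fell. Their median was 0.06 and their mean 0.00, and camera pointed down (adjusted p = 0.673). Of 13 immediate early genes 11 rose and EGR1 fell (median 0.47). JUN and JUND (1.22) had the smallest adjusted p by limma. Camera gave the immediate early list adjusted p = 0.000893, and adjusted p = 0.25 with an estimated correlation. Of 20 interferon-stimulated genes 16 rose and none fell, with IFI44 at 1.59 and ISG20 at 0.97 (median 0.36; camera, adjusted p = 0.000122, and adjusted p = 0.167 with an estimated correlation). Of 11 NF-kB targets 8 rose and BIRC3 fell (median 0.15; camera, adjusted p = 0.0638).

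**Figure D3:**
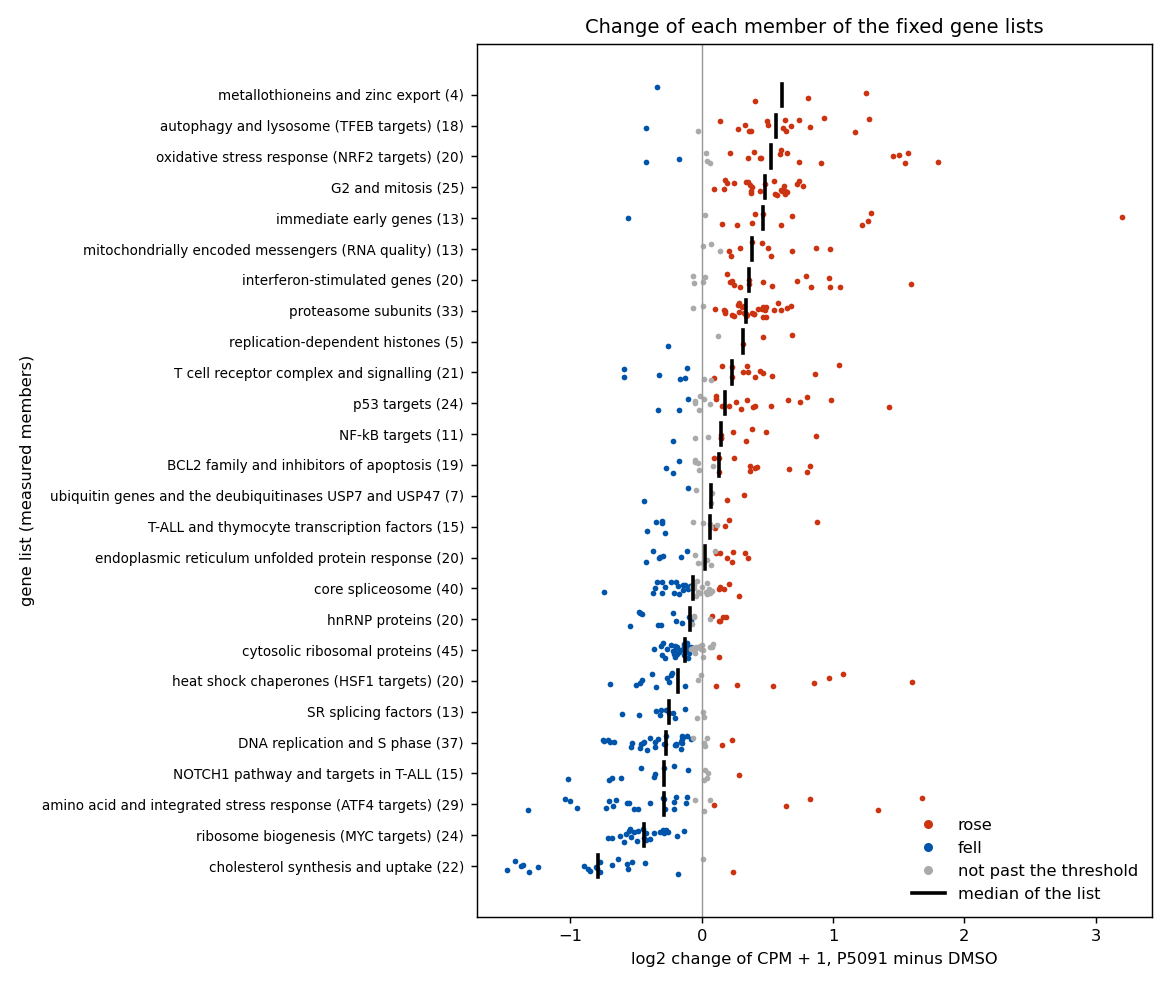
Log2 change of CPM + 1 (P5091 minus DMSO) of each measured member of the 26 gene lists with at least 3 measured members, the number of members in parentheses; points are genes (red rose, blue fell, grey not past the threshold) and black bars are list medians. Cholesterol synthesis has the lowest median (-0.79) and the metallothionein list the highest (0.61).

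In all, 17 of 28 lists passed camera with the preset correlation, 8 up and 9 down. With an estimated correlation 2 passed, cholesterol synthesis and ribosome biogenesis, and fry, which is self-contained, called 24. The estimated correlation allows for members that vary together between libraries. Yet the unadjusted camera p rose in every list, also where that correlation was under the preset 0.01. It went from 0.011 to 0.0479 for p53 targets (correlation -0.0156) and from 8.63e-06 to 0.00856 for autophagy (-0.0227). In the B cell list, with 1 measured gene, it went from 0.0728 to 0.147. Members that vary together are thus not the only source of the rise. Among the named genes ADRM1, PSMD2, MCM2, MCM7, SNRPA, HNRNPH3, KIF20A, CTSD, ACAT2, MYBBP1A, TP53INP1 and RPL4 overlap other listed genes, so part of their reads is uncertain.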

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

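The variance without intensity trend, the correction for GC content and length, the minimum mean of 5 CPM and the minimum of 3 measured members per list were chosen after seeing the data. The 53 named genes, mostly picked by small p, kept direction and limma call in 794 of 794 gene and refit combinations and at 0.01. USP7 lay between -0.47 (RLE size factors) and -0.43 and SRSF6 between -0.38 and -0.33. The count of genes called stayed between 8039 (mean of at least 5 CPM) and 10847 (GC and length corrected), except that a log2 change of at least 1 left 297 (216 higher, 81 lower) and 23 of the named genes, since it removes small changes. Without 1 library it ranged from 9564 to 9995, and 8707 calls held without every library in turn. RLE size factors moved the median of all genes by -0.03 and gave 50.0% higher calls, against 55.6% without them. Deviations of same-numbered libraries correlated at -0.309, -0.326 and -0.147. The highest were DMSO replicate 2 with P5091 replicate 1 (0.46), 3 with 2 (0.399) and 1 with 3 (0.312). With 3 per group, pairing by number or across numbers stays open. With the replicate block 9755 genes passed, 9735 of them called without it, and 18 lists passed camera; only the mitochondrial list changed its call (adjusted p = 0.00929).

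Of 417 combinations of list and setting other than the estimated correlation and fry, 402 kept direction and call. With an estimated correlation 2 lists passed, and the adjusted p rose to 0.167 for the ATF4, NRF2, p53, DNA replication, G2 and mitosis and interferon lists, 0.172 for NOTCH1, 0.0799 for autophagy, 0.195 for epithelial and fibroblast markers, 0.25 for immediate early genes, 0.258 for the proteasome, 0.34 for SR factors, 0.385 for the core spliceosome, 0.488 for hnRNP and 0.507 for ribosomal proteins. Members that vary together are not the only source of that rise. Fry, which is self-contained, called the B cell marker (6.62e-06), BCL2 (1.47e-05), metallothionein (6.53e-05), NF-kB (2.97e-05), histone (0.000381) and T cell receptor (1.87e-05) lists, and the heat shock list upwards (0.0154), against the direction of camera. The mitochondrial list passed with RLE size factors (0.043) and a mean of at least 5 CPM (0.0389), and ranged from 0.0076 (without DMSO replicate 3) to 0.0719 without 1 library, passing also without DMSO replicate 1 (0.0475) and P5091 replicate 1 (0.0437). NF-kB passed with a mean of at least 5 CPM (0.0468) and the epithelial and fibroblast list missed with the GC and length correction (0.053). The cause was not tested. Without 1 library camera gave adjusted p of 0.0174 to 0.0501 for the core spliceosome (highest without P5091 replicate 2), 0.0226 to 0.0559 for hnRNP (highest without P5091 replicate 1) and 0.793 to 0.994 for the ubiquitin list. Its direction turned without DMSO replicate 3, P5091 replicate 1 or P5091 replicate 3, and also with RLE size factors (0.958) and the GC and length correction (0.996), far from the threshold throughout; the cause was not tested. Count models and the scalings that need counts were not run, since the values are CPM; the report uses no filter and library totals alone. In data simulated at this depth 70% of log2 changes of 0.25 were recovered, and what sets that share was not tested.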

Other observations

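The hypoxia, second cell cycle and fatty acid lists were written after the genes of largest change and the fixed lists had been seen, and members seen by then were kept apart from the rest. Their camera p were adjusted over these added lists alone, with the parts seen before included. These adjusted p therefore cannot be compared with those of the fixed lists. Genes of fatty acid synthesis and its regulators fell beside those of cholesterol synthesis. Of 12 members not seen before, 10 fell and LPIN1 rose (median log2 change -0.31; limma's camera, adjusted p = 0.000214, and adjusted p = 0.0923 with an estimated correlation). SCD, a desaturase, changed by -0.86, ACLY, which makes cytosolic acetyl-CoA, by -0.82, and the regulators SREBF2 and SREBF1 by -0.47 and -0.28. A second list of S phase genes had 18 of 24 lower and RAD51AP1 and RPA2 higher (median -0.19; camera, adjusted p = 0.000154, and adjusted p = 0.271 with an estimated correlation). All 27 measured genes of a second list of G2 and mitosis rose (median 0.47). TUBB4B (1.04) and GTSE1 (0.65) had the smallest adjusted p by limma. Camera gave this second list adjusted p = 4.62e-08, and adjusted p = 0.0923 with an estimated correlation.

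Genes induced by low oxygen fell in P5091. Of its members 13 had been seen before the list was written, among them PFKFB4, the hexokinase gene HK2 (log2 change -1.45) and the kinase gene PDK1 (-1.58); DDIT4, VLDLR and STC2 had been seen in the ATF4 list. Their falls are no evidence for the list. A hypothesis is that the hypoxia response may have been less active in the P5091 cells, and it was tested on the 29 measured members not seen before. These members were measured in the same libraries that gave rise to the hypothesis, so this is not an independent test. Of those 29 members 24 fell and SLC2A3, NDRG1 and CITED2 rose, with a median log2 change of -0.46. Camera gave adjusted p = 4.62e-08, and adjusted p = 0.0254 with an estimated correlation. Before adjustment, camera with an estimated correlation gave p = 0.00424 here, against 0.0023 for the cholesterol synthesis list. The adjusted p of these lists rest on different sets of lists, so they do not rank them. VEGFA was at -0.98, SLC2A1 at -0.92 and ADM at -1.33. A trend with GC content or transcript length does not account for the fall, since 1.00 of the whole list's median was left after its removal. A difference in cell density or oxygen between cultures was not tested and stays open, as does any other cause of the fall.

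Long noncoding RNA genes were tested for a rise as a class, and none beyond that of matched protein-coding genes was seen. The tests of explanations leave those open. Of 564 lincRNA genes, at a median of 2.53 CPM, 208 rose and 162 fell, with a median log2 change of 0.05. Only 0.22% of 10000 protein-coding lists matched on expression had a lower median. Those lists ran from 0.04 to 0.18, with a median of 0.11. The lincRNA median thus lay near their low end, and no rise beyond that of such genes was seen. Sense intronic genes had a median of -0.0409 (SE 0.0501), below the lincRNA median by more than that error, which was the bound set beforehand against more unspliced reads. The correction for GC content and length left 1.14 of the lincRNA median, past the bound of 0.8 set beforehand against such a trend. Both bounds were wrong, since the 56 sense intronic genes, at a median of 2.20 CPM, and the lincRNA genes lie near the floor; the limit of 5 CPM used for this reading was set after the values were seen. The matched lists lie at the same low levels, so that comparison covers only genes near the floor. As no rise beyond that of matched genes was seen, no such rise needs explaining. Whether low expression, the share of unspliced reads or a trend with GC content or length shapes the medians of these classes stays open.

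The number of genes past the threshold rests on libraries that differ little within a group. Variation beyond counting noise had a median of 2.36% over genes above 20 CPM (2.74% in DMSO, 1.99% in P5091), a size that technical repeats of the same culture could give, and the labels leave that open. Of the 10 ways to split the 6 libraries into 3 and 3, only the real split itself gave as many genes, with 10163. The highest of the others gave 0 by limma, and at most 244 at an unadjusted p under 0.05. Each of the others mixes DMSO and P5091 libraries, so the difference between treatments widens the spread within its groups. Their low counts are built in and do not show what unrelated libraries would give. A share under 0.05 cannot be reached with 10 splits.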
